A study of Mus musculus with 3 samples.

How the data were processed

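Total RNA of mouse bone marrow-derived dendritic cells (BMDC) was measured on 3 Affymetrix whole-transcript arrays, 1 array per sample. Per the labels' protocols, marrow cells of the inbred strain C57BL/6J were plated at 2000000 cells per well and kept for 9 days in GM-CSF and IL-4, each at 20 ng/ml. RNA was taken with Trizol, and 150 ng per sample was amplified with a whole-transcript kit and labelled with biotin. The labels place all 3 samples in 1 group and name no treatment, genotype or time contrast. They do not say whether the 3 samples came from separate mice or separate cultures, so every spread given here is the spread between these samples and may be technical.

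The deposited values are on the log2 scale and were made by the authors with RMA, per the submitters' processing notes. RMA as a method corrects the background of each array, quantile normalizes the arrays against each other and summarizes the probes of a probe set by median polish. The software, its version and the genome build were not given in the sources used here, and no scanner intensities were used here. The medians of the 3 arrays were 5.91, 5.91 and 5.91. Scale and normalization were judged from these values and from the name of the method, and the values were not centred.

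Of the 35556 probe sets in the table, 21789 name 1 gene in the platform annotation, 1621 name several and 12146 are not listed in it. The annotation is several years old. Entrez identifiers of 21698 probe sets were matched to a current RefSeq gene table, which changed 0 symbols. A probe set naming several genes was not used for any gene. Each of the 19938 genes took the probe set with the highest mean over the 3 arrays. In 201 of the 999 genes with several probe sets, the probe sets disagreed on the call described next.

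Many values were identical between arrays, which bears on every error given here. In 15926 probe sets (44.8%) the 3 deposited values were identical to the last digit, and in another 7877 (22.2%) 2 of the 3 were. The median SD over the arrays was 0.0133 over all probe sets and 0.147 over the 11753 with 3 different values. An SD near 0 is therefore no measure of how precisely a gene was measured.

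A gene was called above background where its value exceeded, in each of the 3 arrays, the 95th percentile of that array's 1210 olfactory and vomeronasal receptor probe sets. These limits were 5.54, 5.54 and 5.55 log2 units. Before the data were examined, 36 gene lists with 525 genes were fixed, of which 478 genes had a probe set of their own. They cover dendritic cell subsets, antigen presentation, cytokine responses, general cell programs and the other cell types that a marrow culture could hold. The share of each of 33 lists above background was set against the share of 51 genes of other tissues (silent tissue genes) by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 33 lists and a threshold of 0.05. A call above background compares probe sets of different binding strength, so it is a rough statement of detection and no measure of transcript amount.

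For 32 lists with at least 8 measured genes, the deviation of each array from the 3-array mean was averaged over the genes above background. The range of the 3 averages was placed among 10000 random lists of the same size, matched on mean level in 10 bins. The resulting percentile describes these arrays and is no p-value, since genes of a list are coexpressed. As a check, 100 lists of 20 genes were drawn from the genes above background, and 3% of them reached the 99th percentile with no shift. With 0.1 log2 units taken from replicate 3, 42% did, and with 0.2, 100% did. These lists came from the same genes as the random lists, so the share without a shift checks the calculation only. A shift in another array was not tried.

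Agreement between arrays was described by correlation across probe sets. Probe sets more variable than others of their level were sought with limma (version 3.58.1), by an F test of each variance against a robust prior with an intensity trend and Benjamini-Hochberg adjustment over all probe sets. The test was tried on simulated data with 35556 probe sets, 200 of them changed in 1 array. With probes summarized by their mean it recovered 100% of the changes at each size with 8 false calls, and with median polish it recovered 0% even of changes of 3 log2 units. A count of 0 from this test on these values thus says nothing about stability.

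The genes named were set by a rule fixed before the data were examined. It took the first 4 measured genes of each list, up to 4 members whose call went against most of their list, the 20 probe sets with the smallest p of the variability test among those that name 1 gene and lay above background in at least 1 array, up to 3 members per list spanning more than 1 log2 unit, all sex-linked genes and H2-Ea. Genes outside the rule are marked where they appear. Alternatives covered the background limit, the call on the mean, the mean of a gene's probe sets, a second quantile normalization, the median of a list, all measured genes, the prior of the variability test and leaving out each array. The limit set by the silent tissue genes is a percentile of the same genes the lists are compared with, so it fixes their share at 3 of 51. A further 3 alternatives were added after the data were seen. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and R 4.3.3, and matplotlib 3.10.9 drew the plots. Left out were comparisons between groups, which 1 group does not allow, and the 47 list genes without a probe set of their own.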

Results

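Genome-wide expression was profiled in BMDC, dendritic cells grown from mouse marrow with GM-CSF and IL-4, on 3 arrays that form 1 group. GM-CSF drives the growth of myeloid cells from marrow and IL-4 steers them toward the dendritic cell fate. No contrast is named, so the data describe which genes these cells expressed and where the arrays differed. Of 19938 genes, 12068 (60.5%) were above background in all 3 arrays, 7616 in none and 254 in 1 or 2 of them. The number of arrays limits the precision of every value. Values are log2 expression, with the SD over 3 arrays.

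Genes of antigen presentation to CD4 T cells were detected broadly. All 12 measured genes of the MHC class II presentation list were above background, among them H2-Aa at 12.57 in each array, H2-Ab1 at 12.36 ± 0.05 (SD, n = 3) and H2-Eb1 at 12.37 ± 0.06 (SD, n = 3), which encode chains of the class II molecules. Cd74, the invariant chain that guides class II molecules to the endosome, had 12.42 in each array. H2-Ea, whose promoter is deleted in C57BL/6 mice, lay below background at 4.50 in each array. All 12 measured genes of MHC class I presentation were above background too, including B2m at 12.79 and the peptide transporter gene Tap1 at 9.89 ± 0.04 (SD, n = 3). The class I genes H2-K1 and H2-D1 of that list had no probe set of their own and were not measured. Against the silent tissue genes, of which 14 of 51 (27.5%) passed the same limit, both shares were higher by Fisher's exact test (adjusted p = 1.29e-05 for each).

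Dendritic cell genes were detected unevenly. Itgax, which encodes the integrin CD11c, had 11.91, 11.92 and 11.91 in replicates 1, 2 and 3, and Ccr7, the receptor that takes mature dendritic cells to lymph nodes, had 10.13 ± 0.39 (SD, n = 3). The transcription factor gene Zbtb46 lay at 6.36 in each array, above this limit but not above one set by the silent tissue genes, whereas Flt3 (5.39 ± 0.13, SD, n = 3), Dpp4, Kmo and Btla lay below it. With 7 of 12 genes above background, the conventional dendritic cell core list did not pass Fisher's exact test (adjusted p = 0.117). With the limit at the 99th percentile of the receptor probe sets, where 4 of 51 silent tissue genes remained, 6 of the 12 were above it and the list passed (Fisher's exact test, adjusted p = 0.00278).

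Both conventional subsets had detected genes and missing ones. In the cDC1 list, Clec9a, a receptor for dead cells, had 9.45 ± 0.22 (SD, n = 3), Batf3 8.29 ± 0.01 (SD, n = 3) and Irf8 10.18 ± 0.13 (SD, n = 3), while the chemokine receptor gene Xcr1 (4.99) and Itgae (5.11) lay below background. In the list of cDC2 and monocyte-derived dendritic cells, Irf4 had 9.65 ± 0.10 (SD, n = 3) and Sirpa 11.63 ± 0.02 (SD, n = 3), while Cd209a (4.76) and Clec4a4 (4.52) lay below background. Each list had 9 of 11 genes above background, a higher share than the silent tissue genes by Fisher's exact test (adjusted p = 0.00223). Of the plasmacytoid list, 7 of 10 genes (70%) were above background (Fisher's exact test, adjusted p = 0.0378), against 60.5% of all genes. These included Bst2 (8.50) and Tcf4 (8.29 ± 0.04, SD, n = 3), which other cells express as well, and not Siglech (5.36), Ccr9 (5.20) or Klra17 (4.50).

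Maturation genes were above background in 18 of 19 cases (Fisher's exact test, adjusted p = 2.37e-06). The costimulatory genes Cd80 and Cd86 had 8.89 ± 0.01 (SD, n = 3) and 8.46 ± 0.03 (SD, n = 3), Cd40 had 7.58 ± 0.01 (SD, n = 3) and Cd83 had 9.66 ± 0.14 (SD, n = 3). The exception was Il12b, a subunit of IL-12, at 5.45 ± 0.14 (SD, n = 3).

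Macrophage genes and the genes of both cytokine lists were detected broadly. All samples were kept in GM-CSF and IL-4, so detection does not show a response to either. All 24 measured genes of the IL-4 response were above background (Fisher's exact test, adjusted p = 1.69e-08), with Arg1, which encodes arginase, at 12.12 in each array, Chil3 at 12.78 in each and Retnla at 12.34 ± 0.32 (SD, n = 3). The mannose receptor gene Mrc1, a member of this list and of the macrophage list, had 10.89 ± 0.22 (SD, n = 3). All 11 genes of the GM-CSF list were above background (Fisher's exact test, adjusted p = 2.23e-05), the receptor genes Csf2ra (10.62 ± 0.10, SD, n = 3) and Csf2rb (11.98 ± 0.04, SD, n = 3) among them. Of the macrophage list, 17 of 19 were (Fisher's exact test, adjusted p = 1.29e-05), including Adgre1, the gene of the F4/80 antigen, at 10.16 ± 0.11 (SD, n = 3), Mertk at 10.61 ± 0.04 (SD, n = 3) and Csf1r at 10.91 ± 0.14 (SD, n = 3). The markers of resident macrophages Cd163 (4.44) and Vsig4 (3.27) were not.

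Sensors of microbial products were detected in 23 of 25 cases (Fisher's exact test, adjusted p = 7.88e-07). Tlr4, the sensor of lipopolysaccharide, had 9.45 ± 0.01 (SD, n = 3), and Clec4e and Cgas lay below background at 5.10 and 5.16. Chemokine genes passed in 14 of 17 cases (Fisher's exact test, adjusted p = 0.000237), with Ccl3 at 12.19, 12.03 and 11.76 in replicates 1, 2 and 3 and Ccl2 at 11.17 ± 0.14 (SD, n = 3), but not Cxcl2, Cxcl3 or Cxcl10. Cytokine genes were above background in 10 of 17 cases (Fisher's exact test, adjusted p = 0.0568). Il1a had 9.97 ± 0.03 (SD, n = 3), while Il10 (3.10) and Il12a (5.13) lay below. Of the chemokine receptor genes 6 of 11 were detected (Fisher's exact test, adjusted p = 0.188). Without replicate 3 both lists passed, with 11 of 17 (Fisher's exact test, adjusted p = 0.0133) and 7 of 11 (Fisher's exact test, adjusted p = 0.047). With the limit at the 99th percentile they passed too, with 9 of 17 (Fisher's exact test, adjusted p = 0.000342) and 5 of 11 (Fisher's exact test, adjusted p = 0.00817).

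Genes of other lineages were detected in part. Of the T cell list, 13 of 14 genes were above background (Fisher's exact test, adjusted p = 3.02e-05), among them Cd3e and Cd3g, which encode parts of the T cell receptor complex, at 8.67 ± 0.48 (SD, n = 3) and 8.11 ± 0.61 (SD, n = 3). With the limit at the 99th percentile of the receptor probe sets, 9 of the 14 T cell genes were above it and the list still passed (Fisher's exact test, adjusted p = 5.52e-05). A limit set by the silent tissue genes, which fixes their own share at 3 of 51, left 8 of the 14. Of the NK list, the granzyme genes Gzma (10.33 ± 0.61, SD, n = 3) and Gzmb (10.38 ± 0.62, SD, n = 3) were above background. So was the receptor gene Klrb1c (6.30 ± 0.31, SD, n = 3), whereas the receptor genes Ncr1 (4.23), Klrd1 (4.89), Klra8 (3.94) and Klre1 (3.39) were not. The NK list had 7 of 12 genes above background (Fisher's exact test, adjusted p = 0.117) and passed with the limit at the 99th percentile, with 6 of 12 (Fisher's exact test, adjusted p = 0.00278). All 7 measured megakaryocyte genes were detected (Fisher's exact test, adjusted p = 0.000751), with the platelet factor gene Pf4 at 10.21 ± 0.55 (SD, n = 3). So were 8 of 10 osteoclast genes (Fisher's exact test, adjusted p = 0.0047), with Acp5 at 11.37 ± 0.12 (SD, n = 3) and Ctsk at 9.24 ± 0.06 (SD, n = 3). The osteoclast genes Calcr (4.87) and Oscar (5.47) lay below background.

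Shares of the remaining lineages did not pass. They were 9 of 19 for neutrophils (Fisher's exact test, adjusted p = 0.188), 5 of 15 for mast cells and basophils (Fisher's exact test, adjusted p = 0.797) and 3 of 13 for B cells (Fisher's exact test, adjusted p = 1). Eosinophil genes reached 2 of 7 (Fisher's exact test, adjusted p = 1), erythroid 3 of 9 (adjusted p = 0.774), stem and progenitor 6 of 11 (adjusted p = 0.188), stromal 5 of 13 (adjusted p = 0.573) and endothelial 4 of 8 (adjusted p = 0.273). The B cell genes Cd79a (4.48 ± 0.19, SD, n = 3) and Ms4a1 (3.80) lay below background, whereas Blnk, a signalling adaptor, had 9.65 ± 0.18 (SD, n = 3). With the limit set by the silent tissue genes, the counts were 3 of 19 for neutrophils, 2 of 15 for mast cells and basophils, 1 of 13 for B cells, 1 of 7 for eosinophils, 0 of 9 for erythroid, 3 of 11 for stem and progenitor, 1 of 13 for stromal and 0 of 8 for endothelial genes, and none of these lists passed. Without replicate 3, 13 of 19 neutrophil genes were above background and that list passed (Fisher's exact test, adjusted p = 0.00419).

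The general programs were detected almost completely. All measured genes passed in the lists of the cell cycle (20 of 20, Fisher's exact test, adjusted p = 1.02e-07) and of immediate early and heat shock genes (14 of 14, Fisher's exact test, adjusted p = 4.34e-06). The same held for cholesterol synthesis (12 of 12, Fisher's exact test, adjusted p = 1.29e-05), the unfolded protein response (10 of 10, Fisher's exact test, adjusted p = 4.78e-05) and housekeeping (12 of 12, Fisher's exact test, adjusted p = 1.29e-05). Hypoxia and glycolysis genes passed in 14 of 15 cases (Fisher's exact test, adjusted p = 1.6e-05) and interferon-stimulated genes in 17 of 19 (Fisher's exact test, adjusted p = 1.29e-05), with Adm (5.21 ± 0.02, SD, n = 3) and Mx2 (4.98 ± 0.12, SD, n = 3) below background. In all, 21 of 33 lists had a higher share than the silent tissue genes. Of all 19938 genes, 60.5% were above the same limit, also more than the 27.5% of the silent tissue genes. Passing thus does not set a list apart from genes in general, and no list was tested against that share. Of the sex-linked genes, the Y-linked Kdm5d (7.33), Uty (7.81 ± 0.02, SD, n = 3) and Eif2s3y (8.89) were above background in every array, and Xist, the RNA that silences an X chromosome in female cells, was below it at 4.09.

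**Figure D1:**
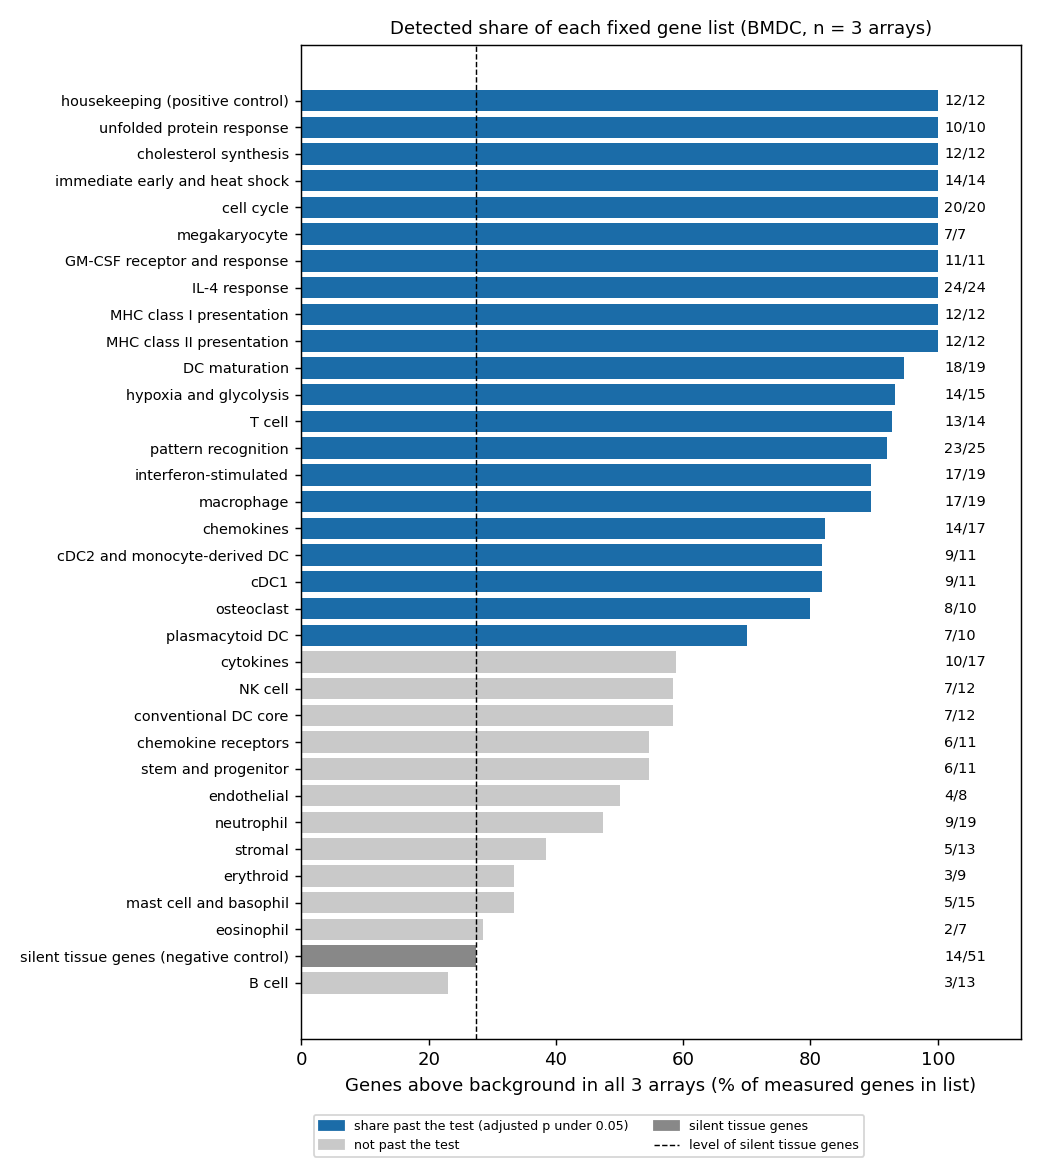
Percent of the measured genes of each fixed list that were above background in all 3 arrays (x axis), by list (y axis), with the counts at the right. Blue bars passed Fisher's exact test against the silent tissue genes, light grey bars did not, and the dashed line marks the 27.5% of the silent tissue genes. All 12 genes of MHC class II presentation and 3 of 13 B cell genes were above background.

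The arrays resembled each other across probe sets, with replicate 3 the farthest from replicate 1. Pearson's r over all probe sets, which are not independent replicates, was 0.996 for replicates 1 and 2, 0.994 for 1 and 3 and 0.995 for 2 and 3. Among the 12068 genes above background, 4 differed by more than 1 log2 unit between replicates 1 and 2, 59 between 1 and 3 and 7 between 2 and 3. Over all probe sets 730 spanned more than 1 unit, of which 644 are not listed in the annotation.

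Lymphocyte genes were lowest in replicate 3. Over the 7 detected NK genes the mean deviation was 0.37, 0.14 and -0.51 log2 units in replicates 1, 2 and 3, a range of 0.88 or 1.84-fold, and all 7 were lowest in replicate 3. Over the 13 detected T cell genes it was 0.22, 0.05 and -0.27, and 10 of the 12 that were not identical between arrays were lowest in replicate 3. Gzmb, a protease of killer cells, had 10.89, 10.56 and 9.69 in replicates 1, 2 and 3, and Il2rb, a chain of the IL-2 and IL-15 receptors, had 9.81, 9.47 and 8.42. Cd8a, placed in the cDC1 list and also a T cell gene, had 9.37, 8.87 and 8.18. None of the 10000 random lists had a range as large as that of either list.

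Cell cycle genes were lowest in the same array, as were those detected mast cell and basophil genes that differed between arrays. Over 20 cell cycle genes the deviation was 0.34, 0.10 and -0.44, a range of 0.77 or 1.71-fold, and 19 of the 20 were lowest in replicate 3. Mki67, a marker of dividing cells, had 8.50, 8.18 and 7.38, and Top2a, the topoisomerase that untangles chromosomes before division, had 8.06, 7.61 and 6.77. Over the 5 detected mast cell and basophil genes the range was 0.61 or 1.52-fold, and 3 of the 5 were lowest in replicate 3. These were the basophil protease gene Prss34 (7.75, 8.24 and 6.38), Gata2 (6.99, 6.99 and 6.42) and Hdc (6.30, 6.33 and 5.73), whereas Tpsb2 (5.78) and Il13 (5.91, named after its values were seen) were identical in the arrays. Cpa3, a mast cell protease, had 7.38, 7.54 and 5.38, and so lay above background in 2 arrays. The same was true of the neutrophil genes Ly6g (6.73, 6.80 and 4.86), Lcn2 (7.98, 6.69 and 5.12) and Retnlg (7.35, 7.11 and 5.55). None of the 10000 random lists reached the range of the cell cycle list or of the mast cell list.

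The hypoxia list went the other way. Over its 14 detected genes the deviation was -0.18, 0.01 and 0.17, a range of 0.36 or 1.28-fold, and 11 of the 12 genes not identical between arrays were lowest in replicate 1. Vegfa, a growth factor for blood vessels, had 9.07, 9.49 and 10.09, and Bnip3, a mitochondrial protein induced by low oxygen, had 7.85, 8.43 and 8.87. The unfolded protein response list was lowest in replicate 3, with deviations of 0.21, 0.01 and -0.22 and 7 of the 9 genes not identical between arrays lowest there, and within it Asns, asparagine synthetase, had 8.88, 8.17 and 7.45. The megakaryocyte list had too few genes for this description, and its 7 genes differed in direction. Pf4 (10.65, 10.39 and 9.59), Ppbp (8.04, 7.56 and 6.64) and Vwf (8.37, 8.12 and 7.73) were lowest in replicate 3, Treml1 (7.66, 7.73 and 7.75) was highest there, Clec1b had 8.68, 8.67 and 8.67, and Itga2b (6.33) and Gp9 (5.61) were identical in the arrays. Vwf, Treml1 and Clec1b were named after their values were seen.

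Of the 32 lists, 11 had a range at or over the 99th percentile of the random lists, and replicate 3 was lowest in 10 of them. Replicate 3 was also lowest in most lists under that percentile, housekeeping (-0.052) and the silent tissue genes (-0.0095) among them. Exceptions were MHC class II presentation and immediate early and heat shock (lowest in replicate 1). Others were erythroid, stromal, pattern recognition and interferon-stimulated genes (lowest in replicate 2). Being lowest in replicate 3 thus does not by itself set the shifted lists apart. Of the 11, the 5 not described above were chemokine receptors (range 0.37), chemokines (0.26), DC maturation (0.19), macrophage (0.18) and the IL-4 response (0.14). In these 5, in that order, 3 of 4, 9 of 11, 11 of 18, 9 of 16 and 14 of 20 not identical genes were lowest in replicate 3. Lists share members, with 27 genes in 2 or more lists, so the shifted lists are not separate observations. Ccl17 and Ccl22, for example, are in DC maturation, the IL-4 response and chemokines. Without replicate 3, the range fell below the 99th percentile for IL-4 response (0.019), chemokines (0.060) and chemokine receptors (0.071), and without replicate 2 for DC maturation (0.083). MHC class II presentation had a range of 0.0031, smaller than 9911 of the 10000 random lists, pattern recognition 0.0059, and housekeeping genes 0.094 at the 91.0th percentile. A small range of the mean does not show that single genes were alike, since members can go opposite ways. H2-Oa (6.47, 6.53 and 6.19) and H2-Ob (6.56, 6.59 and 6.89), class II genes named after their values were seen, did so in replicate 3.

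**Figure D2:**
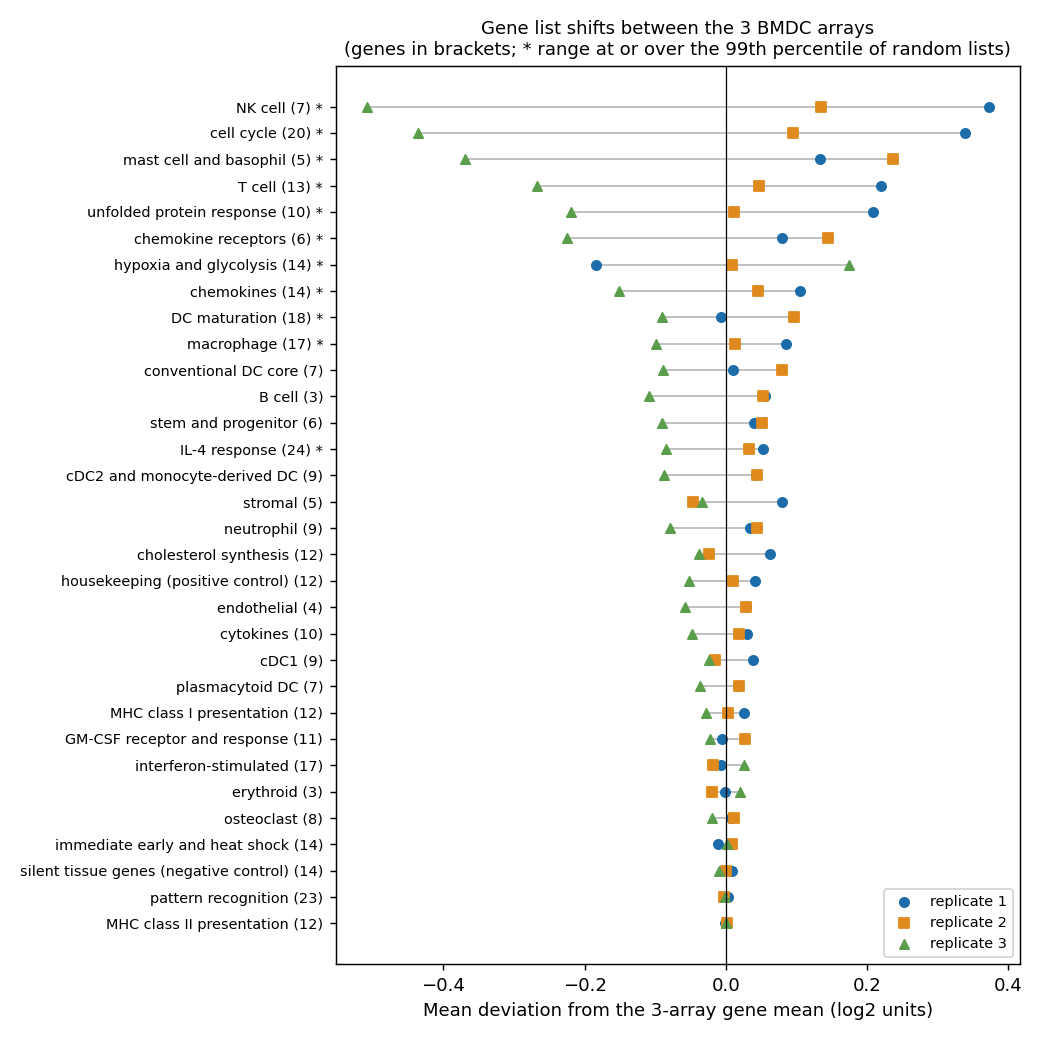
Mean deviation of each array from the 3-array gene mean in log2 units (x axis), by fixed gene list (y axis, detected genes in brackets). Symbols are the 3 arrays and a star marks a range at or over the 99th percentile of 10000 random lists. The NK list runs from 0.37 in replicate 1 to -0.51 in replicate 3.

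Dcn, Sparc, Lox and Bgn, which have roles in the extracellular matrix and were named for their small p, were high in replicate 1. Dcn, a proteoglycan of connective tissue, had 8.12, 5.36 and 5.41 in replicates 1, 2 and 3, Sparc had 7.64, 5.34 and 5.78, Lox, which crosslinks collagen, had 7.58, 4.47 and 4.63, and Bgn had 8.19, 5.33 and 5.31. Igfbp7 had 7.91, 6.02 and 5.92, and Pdgfra, a receptor of mesenchymal cells, had 5.71, 5.59 and 5.59. The collagen genes Col1a1 (6.94, 6.69 and 6.76), Col1a2 (6.53, 6.36 and 6.36) and Col3a1 (6.10 in each) differed by less than Dcn. Of the 72 genes that were above background in at least 1 array and spanned more than 1 log2 unit, 60 were highest in replicate 1 and 62 lowest in replicate 3. Lox, Dcn and Bgn were above background in replicate 1 alone.

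No probe set passed the variability test. limma called 0 of 35556 probe sets, with 20 at an unadjusted p under 0.05, a smallest p of 0.043 for Lox and a smallest adjusted p of 0.616. Of the probe sets that name 1 gene and lay above background in at least 1 array, the 20 with the smallest p, from 0.043 to 0.068 and none of which passed, were those of Lox, Il6, Bgn, Dcn, Sparc, Mcpt8, Ly6g, Lcn2, Trdn, Olfr1331, Car4, Olfr1085, Cpa3, Igfbp7, Gja1, Grem1, Bex1, Ddr2, Cyp1b1 and Olfr316. Adjusted over the list alone, 0 genes passed in each of the lists. In simulated data in which 70.9% of probe sets were identical between arrays, the test recovered 0% of the changes, so the count does not show that the arrays were alike.

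**Figure D3:**
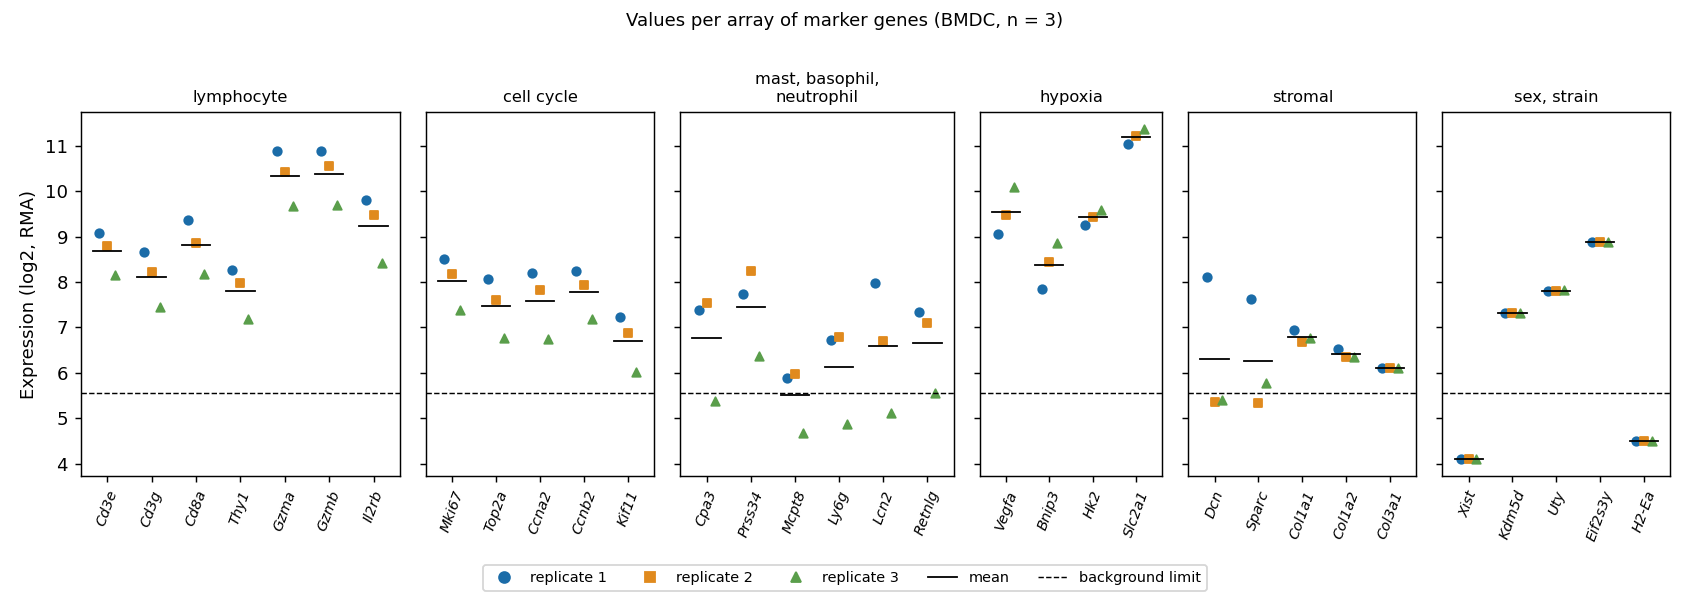
Log2 expression (y axis) of named marker genes (x axis) in each of the 3 arrays, with a bar at the mean and a dashed line at the highest of the 3 background limits, 5.55. Gzmb had 10.89, 10.56 and 9.69 in replicates 1, 2 and 3, and Dcn had 8.12, 5.36 and 5.41.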

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

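The alternatives using only genes or probe sets with 3 different values, and those using genes above background in at least 1 array in the shift analysis, were chosen after seeing the data. No paired analysis was possible because there is 1 group. No result reversed. A second quantile normalization left 21 lists past the detection test and kept all 11 of the shifted lists. With the limit at the 99th percentile of the receptor probe sets, the detected counts of conventional DC core, NK cell, cytokines and chemokine receptors were 6, 6, 9 and 5, and with the limit from silent tissue genes 5, 6, 9 and 5, and all 4 lists then passed, since fewer silent tissue genes did (4 and 3 of 51, the latter fixed by that limit's own construction). At these 2 limits other counts were lower and did not pass, with 3 and 3 for neutrophil, 2 and 2 for mast cell and basophil, 1 and 1 for B cell and for eosinophil, 0 and 0 for erythroid and for endothelial, 3 and 3 for stem and progenitor and 2 and 1 for stromal. T cell had 9 and 8 in place of 13 and passed at both. So did megakaryocyte and plasmacytoid DC (each 5 and 5 in place of 7), cell cycle (16 and 16 in place of 20) and chemokines (11 and 11 in place of 14). Stromal had 8 on the mean and did not pass. Called on the mean of the 3 arrays, neutrophil (13) and chemokine receptors (7) passed. Leaving out each replicate, the count was 9 to 13 for neutrophil, 10 to 11 for cytokines and 6 to 7 for chemokine receptors, each highest without replicate 3. Over probe sets above background in all 3 arrays, the lowest r was 0.992 and 112 spanned more than 1 log2 unit. With 1 replicate left out the lowest r was 0.994 to 0.996 and the count 236 to 426, fewer because 2 arrays span less than 3.

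For the shifts, the median in place of the mean gave IL-4 response 0.037 (98.9th percentile); the cause was not tested. Only genes with 3 different values gave macrophage 0.34 and chemokine receptors 0.74, as genes with equal values in 2 or 3 arrays were left out, and 8 of the 11 lists stayed at or over the 99th percentile among 25 with enough genes. With genes above background in at least 1 array, neutrophil (0.64), stromal (0.72, with Dcn and Sparc then counted) and cytokines (0.25) joined the 11. Leaving out each replicate gave ranges of 0.083 to 0.19 for DC maturation, 0.071 to 0.18 for macrophage, 0.019 to 0.14 for IL-4 response, 0.11 to 0.61 for mast cell and basophil, 0.17 to 0.49 for T cell, 0.24 to 0.88 for NK cell, 0.24 to 0.77 for cell cycle, 0.060 to 0.26 for chemokines, 0.071 to 0.37 for chemokine receptors, 0.17 to 0.36 for hypoxia and glycolysis and 0.20 to 0.43 for unfolded protein response. Of the 11 lists, 11, 10 and 8 stayed at or over the 99th percentile without replicate 1, 2 and 3. The variability test called 0 probe sets in each of its 9 settings, with 0 to 707 at an unadjusted p under 0.05. Of 203 named gene calls, 30 were lost at the 99th percentile limit and 32 at the limit from silent tissue genes, Zbtb46 among the latter, so calls within about 1 log2 unit of the limit are weak.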

Other observations

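The tests of identical values and of stromal cells were chosen after the results were seen, and those of the further gene lists after the shifts were seen but before the values of their own genes. The genes named in this part outside the fixed rule were chosen after their values were seen.

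The osteoclast list held genes of cell fusion. Atp6v0d2, a proton pump subunit needed for fusion of osteoclasts and giant cells, had 12.44 ± 0.02 (SD, n = 3), Ocstamp 11.37 ± 0.16 (SD, n = 3) and Dcstamp 10.75 ± 0.13 (SD, n = 3). Gpnmb, a glycoprotein of macrophages and osteoclasts, had 13.04 (n = 3), and the complement genes C1qb and C1qc had 12.40 ± 0.07 (SD, n = 3) and 11.75 ± 0.17 (SD, n = 3). Of the cytokine genes, Il1rn, which encodes the IL-1 receptor antagonist, had 9.90 ± 0.15 (SD, n = 3), while Il23a (5.10) and Ifnb1 (3.58) lay below background.

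In 44.8% of probe sets the 3 arrays had identical values. Rounding was tested through the non-zero differences between arrays, of which 0.229% were under 0.001 log2 units, so the values do not crowd at a rounding step. Median polish was simulated over 3 arrays with 25 probes per set, and it left 78.8% of sets identical with no true difference and 6.7% with a true SD of 0.3 between arrays. The observed share lies between these, so the summary method is a candidate explanation, but with 10 probes the simulated share was at most 15%, with 4 probes it was 0%, and RMA was not rerun. No biological explanation was tested.

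Lymphocyte and cell cycle genes were lower in replicate 3. A second quantile normalization kept all 11 of the shifted lists, but the arrays had medians of 5.91 each before it, so it had little scale to remove. A further list of cytotoxic lymphocyte genes was also lowest in replicate 3, with a range of 0.56 at percentile 100. That range covers the 12 of its 20 measured genes that were above background in all 3 arrays. The rest, such as Gzmk (4.82), Cd160 (4.71) and Klrc1 (3.45), were left out. Of the 11 covered genes that were not identical between arrays, 9 were lowest in replicate 3. Ifng had 8.10, 7.59 and 7.08, and Cd226 went the other way with 8.72, 8.72 and 8.83. A smaller share of lymphocytes in that sample may give this, but lower expression per cell would too, and bulk RNA leaves both open. A technical difference between the samples is open as well.

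Dcn, Sparc, Lox and Bgn were high in replicate 1, as were Igfbp7 (7.91, 6.02 and 5.92) and Timp1 (8.43, 6.68 and 6.35). Col3a1 (6.10 in each array) and Postn (5.12, 5.07 and 5.07) differed less, but they do not speak against a stromal difference. Postn lay below background in every array, and identical values as for Col3a1 do not show that a gene was measured precisely. Grem1 (5.81, 5.07 and 4.95), Gja1 (5.65, 4.87 and 4.87) and Ddr2 (5.73, 5.02 and 4.92) were above background in replicate 1 alone. They were named for their small p, and others named so, such as Trdn (4.68, 5.29 and 5.94), were highest in another array. The stromal list itself had a range of 0.13 over its 5 detected genes, at percentile 91.3 and so under the 99th. That range left out Dcn, Sparc and Lepr, which were not above background in all 3 arrays, so it cannot speak against a stromal difference. With genes above background in at least 1 array, the range was 0.72 over 9 genes, at percentile 100. Of the 11 measured stromal genes other than Dcn and Sparc, 9 were higher in replicate 1 than in the mean of the others. The lowest difference was 0, the highest was 0.78, for Lepr, and the median was 0.093 log2 units. That median is neither 0 nor near the change of Dcn, with genes close to background. More stromal cells in that sample, higher expression per cell and a technical difference therefore cannot be told apart.

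Beyond these patterns, the other further gene lists gave the following. The mean of the amino acid response genes was lowest in replicate 3, with a range of 0.24 over 21 genes, at percentile 99.99. Of the 21 genes, 14 were lowest there alone, and Sars, Iars and Eprs were lowest there in a tie with replicate 2. Nars was lowest in replicate 2. Wars (9.83, 9.92 and 10.04), Cebpb (8.88, 9.01 and 9.01) and Slc7a11 (10.58, 10.60 and 10.60) were lowest in replicate 1. The mean of the further hypoxia targets was highest in replicate 3, with a range of 0.12 over 16 genes, at percentile 97.5, under the 99th that had been set. Of the 13 that were not identical between arrays, 11 were lowest in replicate 1, ties with replicate 2 included. Ddit4 (6.77, 6.61 and 6.55) and Narf (6.89, 6.85 and 6.85) were highest there.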
